A study of Gallus gallus with 30 samples.

How the data were processed

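Total RNA of whole chicken embryos (Gallus gallus, Nera line, wild type, yolk and amnion removed) was measured at 15 stages, with 2 pools of embryos per stage and 1 Affymetrix Chicken Genome Array per pool, 30 arrays in all. Per the labels the RNA was extracted with a lipid tissue kit, labelled with biotin by in vitro transcription from the 3' end, and the replicates are biological. How many embryos made up a pool is not given in the sources used here.

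The deposited intensity values are linear signals of the MAS5 algorithm per probe set, according to the submitters' processing notes. The version and settings of that software are not given in the sources used here. The mean of the values on each array, after trimming 2% at each end, was 500, which was checked on every array. The deposited values were used as they are, were converted to log2, with any value of 0 or below set to the smallest positive value of the array. The raw probe intensities were not used here.

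The platform has 38535 probe sets, of which 37693 are for chicken, 689 for other organisms, 57 for reporter genes and 96 are controls. Gene symbols came from the platform's own table. Of the chicken probe sets 27166 had 1 symbol, 177 several and 10350 none. The gene table of the GRCg7b assembly was used to check names. It held the gene identifier of 26851 of the probe sets with 1 symbol, and 0 symbols were changed. Genes are identified by symbol, with 1 probe set for each value. For VSTM2A, KRT5, GCG, HSPB9 and SLC7A9 different parts of the rule for named genes picked different probe sets. Probe sets were kept when their signal reached the 40th percentile of the array on at least 2 arrays, which left 29600, of which 22471 had 1 symbol, from 12146 genes.

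The background of an array was the 95th percentile of its 689 other-organism probe sets, a rule added after the data had been seen. It ranged from 25.4 (HH2 replicate 1) to 47.2 (HH24 replicate 1), and the median chicken signal from 62.2 to 97. Where a gene was at or below background on both arrays of its dimmer stage, the fold was bounded with the background in place of the signal. The same was done where 1 of these arrays was below background. The 3' to 5' ratios of control probe sets were computed per array.

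A linear model with 15 stage means was fitted to log2 signals with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), with 15 residual degrees of freedom. The stage effect was tested by the moderated F statistic. Contrasts were HH16 minus HH1, HH38 minus HH16 and the 14 steps between neighbouring stages, with Benjamini-Hochberg adjustment within each contrast. A probe set was called at an adjusted p below 0.05 and at least a 2-fold change. HH16 was apart from both ends when both main contrasts were called in opposite directions. The count was set against the product of shares. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

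There were 36 gene lists, written from textbook knowledge, and 35 had at least 5 measured members. They covered epiblast, primitive streak, somite, 3 groups of Hox genes, neural crest, neural progenitor, neuron, glia, cardiac and skeletal muscle, erythroid, globin, endothelium, liver, yolk sac endoderm, oocyte, germ cell, leukocyte, cartilage, bone and connective tissue, lens, retina, pigment cell, epidermis, limb bud, kidney, gut and pancreas, lung, cell cycle, ribosomal proteins, oxidative phosphorylation, glycolysis, heat shock and the W chromosome (4 measured members, counted and not tested). Lists were tested against all other genes with camera (correlation preset at 0.01, variance trend, the kept probe set with the highest mean for each gene), adjusted over lists and both main comparisons, and again with an estimated correlation. With fry, lists were tested for a change in 1 direction, without comparison with other genes. The first stage of a list was the first from which camera called it against HH1 at that and every later stage. All 14 of these comparisons share the HH1 arrays. The list tests at the 14 steps, 490 in number, were added after the data had been seen. Of these, 119 were called and 24 also with an estimated correlation. The onset of a Hox gene was the first stage called higher than HH1, and its rank correlation with paralog number was tested by permutation with 1e+05 resamples.

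Named genes followed a rule. In each main comparison these were the 10 largest rises and falls among called probe sets with 1 symbol, with both arrays of one stage above both of the other and a higher stage mean above the median of kept probe sets. At each step the rule took 2 and 2, and for HH16 apart from both ends 8 and 8 by the smaller difference. From each list it took the 3 members with the largest absolute change, and all globins and Hox genes. The rule ranks by the fitted change, which for genes below background at the dimmer stage rests on signals under the floor. The genes it names are therefore not the largest changes by their bounds. Exceptions were made after the values were seen. Of 55 called entries at the steps, 24 lost their call when 1 array was left out. These are not described as step changes, except HBZ at HH6 and HH32 and COL23A1 at HH34, each given with that limit. For the step to HH16 0 genes remain. Also left out on this ground were 21 of 178 list entries and 2 of 32 entries apart from both ends. Further list entries were left out for length. MYBPC3, the heart form of its protein, is counted in the skeletal muscle list but not described as a muscle gene. Stage signals of other stages (TBXT, ALB, HBZ and others) were also chosen after the values were seen.

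Alternatives changed 1 choice at a time. They were quantile normalization, scaling to a common 75th percentile, no filter, a filter at the 60th percentile, a pseudocount of 22.4, no variance trend, robust variance, array weights, a block for the replicate number, each of the 30 arrays left out in turn, a fit on the arrays of the compared stages alone, adjusted p alone, adjusted p below 0.01, an estimated correlation, fry, the mean of all probe sets of a gene and, for Hox genes, the stage of the highest mean. Contrasts, thresholds, lists, the gene rule and these alternatives were set before the data were examined. HH34 in place of HH38, HH2 in place of HH1 and leaving out the 4 arrays of HH8 and HH24 were chosen after seeing the data.

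The fit was tested on simulated data with the spread of these arrays. Of probe sets changed 2-fold, 4-fold and 8-fold, 19 of 67, 45 of 67 and 56 of 66 were called, and 2 unchanged ones were. Of those changed 2-fold 30 passed the adjusted p, and the rule of at least a 2-fold estimate also limits this count. All others of the 29600 probe sets were left unchanged, and the change was set at HH16 alone. In the data 12751 passed the adjusted p between HH1 and HH16, which loosens the adjustment. The simulated shares therefore do not give the sensitivity of that comparison. In simulated lists camera called the 1 shifted list of 35 and 0 others. The simulated noise was independent between genes, while the estimated correlation in the data was 0.84 for the globin list. The simulation therefore does not test how often camera calls lists of correlated genes in error. Other-organism, reporter and control probe sets were left out of the comparisons.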

Results

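RNA of whole chicken embryos was measured at 15 stages of the Hamburger and Hamilton series, from HH1, the blastoderm of the freshly laid egg, to HH38, a late embryo with formed organs. The stages were HH1, HH2, HH4, HH6, HH8, HH9, HH11, HH14, HH16, HH19, HH24, HH27, HH32, HH34 and HH38. Eggs of the Nera line were incubated at 37.5 degrees, yolk and amnion were removed, and RNA was pooled over embryos for each sample. The labels give the sex as mixed and describe the pools of a stage as biological replicates. Each stage had 2 pools, each on 1 Affymetrix Chicken Genome Array, which makes 30 arrays. On every array the mean signal over probe sets, after trimming 2% at each end, was 500. Between 24484 and 27448 of the 37693 chicken probe sets (65% to 72.8%) lay above the background of their array. The number of arrays limits the precision of every value below.

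The course was read as 2 parts, from HH1 to HH16 and from HH16 to HH38, and as 14 steps between neighbouring stages. It was also read by the stage from which each gene list stayed apart from HH1. The series is known for its comparison of organogenesis stages between vertebrates, and HH16, an embryo with head, heart, somites and limb bud rudiments, was taken as its middle. Stage signals are geometric means of 2 arrays. Changes are log2 differences with their standard error from limma, n = 2 arrays per stage, and adjusted p refers to limma's moderated test throughout. A probe set was called when its adjusted p was below 0.05 and its change at least 2-fold. Where a gene was below background on both arrays of its dimmer stage, its change is given as a lower bound ("at least N-fold"). Where 1 of these 2 arrays was below background, background took its place in the same bound.

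Arrays of the same stage correlated at r = 0.94 (HH8) to 0.958 (HH27) over probe sets, and 23 of the 30 arrays were most similar to the other array of their stage. HH1 and HH38 correlated at r = 0.713. The first principal component held 39.8% of the variance. Of 29600 probe sets tested, 20412 (69%), from 10245 named genes, differed between stages. Their highest stage mean fell most often at the ends of the course, 4372 (21.4%) at HH1 and 3453 (16.9%) at HH38, and least often at HH14 (473, 2.32%).

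The first steps of the course called the most probe sets. From HH1 to HH2, ALDH1A1, which makes retinoic acid, rose at least 7.99-fold to a signal of 246.1, and the glucose transporter SLC5A1 rose at least 15.8-fold, with 1 of its 2 HH1 arrays above background. OSGEPL1 fell at least 6.91-fold, with 1 of its 2 HH2 arrays above background. Heat shock and immediate early genes moved up as a list over this step, with 4 of 14 higher and 0 lower (camera adjusted p = 0.00346, 0.086 with an estimated correlation), and the collagen chaperone SERPINH1 went from 178.3 to 1999. Yolk sac genes had 5 of 16 higher and 2 lower (0.0239, 0.257 with an estimated correlation). From HH2 to HH4, APOB, the protein core of yolk-derived lipoproteins, rose at least 372-fold (adjusted p = 3.11e-12), reaching 11170 and 10070 on the HH4 arrays, and the protease inhibitor SERPINA10 rose at least 46.7-fold. SERPINB2 (at least 10.2-fold) and the pantetheinase VNN2 (at least 12.4-fold) fell over the same step. Liver genes moved up as a group at this step, with 17 of 25 higher and 0 lower (camera adjusted p = 8.39e-14, and 0.0223 with an estimated correlation). Of 16 genes of yolk sac endoderm, the extraembryonic tissue that takes up yolk, 10 were higher and 2 lower (2.4e-05, and 0.0341 with an estimated correlation). Genes of the first Hox paralog groups (6 of 8 higher, 1.96e-08 and 0.0238) and of the limb bud list (10 of 19 higher, 0.000488 and 0.0223) also moved up.

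Between HH4 and HH9 few genes were called. The thrombin receptor gene F2RL2 rose at least 4.76-fold from HH4 to HH6, while TANK (-1.32 ± 0.188) and the small heat shock gene HSPB9 (-1.19 ± 0.171) fell. Globin genes moved up as a list at HH6, with 2 of 5 higher and 0 lower (camera adjusted p = 4.13e-08, 0.111 with an estimated correlation). The HH6 arrays differed, with HBZ at 676.2 and 2392, and its call ended without HH6 replicate 2 (adjusted p = 0.608) and without either HH4 array (0.167 and 0.176), and also without any 1 array of HH11, HH14, HH16, HH19, HH27, HH32, HH34 or HH38 (0.0503 to 0.0542). ASTL, an astacin-like protease, fell from 13670 to 3466 between HH6 and HH8 (-1.98 ± 0.242). At HH9, when the heart tube forms, the myosin genes MYH15 (2.30 ± 0.298) and MYL2 (2.02 ± 0.286) rose from HH8, and MYH15 went from 146.7 to 721.8. Cardiac muscle genes moved up as a list (3 of 18 higher, 6.93e-05, 0.111 with an estimated correlation).

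The step from HH9 to HH11 was again large. LYVE1, a receptor of lymphatic and some other endothelium, rose at least 11.1-fold and the posterior Hox gene HOXD10 at least 18.2-fold. The muscle gene MYBPC1 fell at least 5.36-fold. Hox genes of groups 9 to 13 moved up (6 of 11 higher, camera adjusted p = 2.6e-05, 0.0341 with an estimated correlation), and cardiac muscle genes had 6 higher and 1 lower (0.000427, 0.16 with an estimated correlation). Genes of yolk sac endoderm moved down, with 6 of 16 lower and 1 higher (7.35e-06, 0.0292 with an estimated correlation). Liver genes had 9 of 25 lower and 0 higher (1.53e-06, 0.116 with an estimated correlation), and genes of the primitive streak 5 of 23 lower (0.000905, 0.0661 with an estimated correlation). From HH11 to HH14, GCG, the gene of glucagon, rose at least 7.77-fold, and ASL1, whose product is the delta crystallin of the lens, rose by 4.42 ± 0.519 from 81.28 to 1743. ALPPL fell at least 5.15-fold and the apolipoprotein gene APOA4 fell at least 11.9-fold, with 1 of its HH14 arrays above background. The liver list fell further over this step (10 of 25 lower, 3.11e-17, 0.0127 with an estimated correlation).

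From HH16 to HH34 the steps called between 18 and 302 probe sets each. MYT1, a transcription factor of neuronal precursors, rose at least 9.38-fold from HH16 to HH19 with 1 of 2 HH16 arrays above background, and 10 of 23 neuron genes were higher and 0 lower (camera adjusted p = 1.91e-17, 0.00092 with an estimated correlation). From HH19 to HH24 the secreted phosphoprotein gene SPP2 rose at least 8.94-fold with 1 of 2 HH19 arrays above background, and PRTG, an early neural surface protein, fell from 3625 to 828 (-2.13 ± 0.124). LIN28B, an RNA-binding protein that blocks let-7 microRNA, fell by 1.87 ± 0.301 from HH24 to HH27. ALB, the gene of serum albumin, rose from 695.6 to 22220 between HH27 and HH32 (5 ± 0.34, adjusted p = 1.18e-08), a step with 15 of 25 liver genes higher and 0 lower (8.21e-23, 0.0049 with an estimated correlation). COL23A1 fell at least 6.83-fold over this step. It then rose to HH34, a call that ended without any 1 array of HH32 or HH34 (log2 changes of 2.68 to 2.91). From HH32 to HH34, LGALS1A, a galectin gene, rose from 1122 to 3212 (1.52 ± 0.137). From HH34 to HH38 the plasma protein gene PIT54 rose at least 25.4-fold and the keratin gene KRT6A at least 61.3-fold, while HINTW (at least 468-fold) and HNRNPKL (at least 42.4-fold) fell. Of 12 epidermis genes, 8 were higher and 0 lower at HH38 than at HH34 (8.79e-13, 0.00615 with an estimated correlation). Both HH38 arrays stood apart in the actin 3' to 5' ratio (2.48 and 2.99 against 1.54 to 2.01) and in W-linked genes, which read below background by their brightest probe sets.

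Counts per step were 3206 probe sets at HH2 (1607 higher, 1599 lower), 2395 at HH4 (1847, 548), 1410 at HH11 (652, 758) and 1126 at HH38 (687, 439). The other 10 steps called between 18 (HH34) and 302 (HH32) each. In course order they gave 96 probe sets at HH6, 56 at HH8, 52 at HH9, 137 at HH14, 21 at HH16, 258 at HH19, 224 at HH24, 273 at HH27, 302 at HH32 and 18 at HH34. Stages are not evenly spaced, so these are changes per step and not per hour. Several of the smaller counts rested on single arrays. HH6 had 211 without its replicate 1 and 55 without its replicate 2. HH8 had 21 without HH6 replicate 1, 153 without HH6 replicate 2 and 165 without HH8 replicate 2, and HH9 had 100 and 146 without HH8 replicates 1 and 2 and 187 without HH9 replicate 1. HH14 had 85 without HH11 replicate 1, HH16 had 65 without HH14 replicate 2 and 63 without HH16 replicate 2, and HH19 had 170 without HH16 replicate 2. HH27 had 124 and 593 without HH24 replicates 1 and 2, and 141 and 151 without its own, and HH34 had 10 without HH32 replicate 2 and 35 and 31 without its own replicates 1 and 2. Quantile normalization changed the split of higher and lower calls at HH8 from 37 and 19 to 28 and 27, at HH9 from 33 and 19 to 56 and 15 (17 and 21 without the variance trend), and at HH24 from 168 and 56 to 126 and 90. At HH34 the split was 10 and 8, and 1 and 8 without the variance trend and 33 and 40 with array weights.

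**Figure D1:**
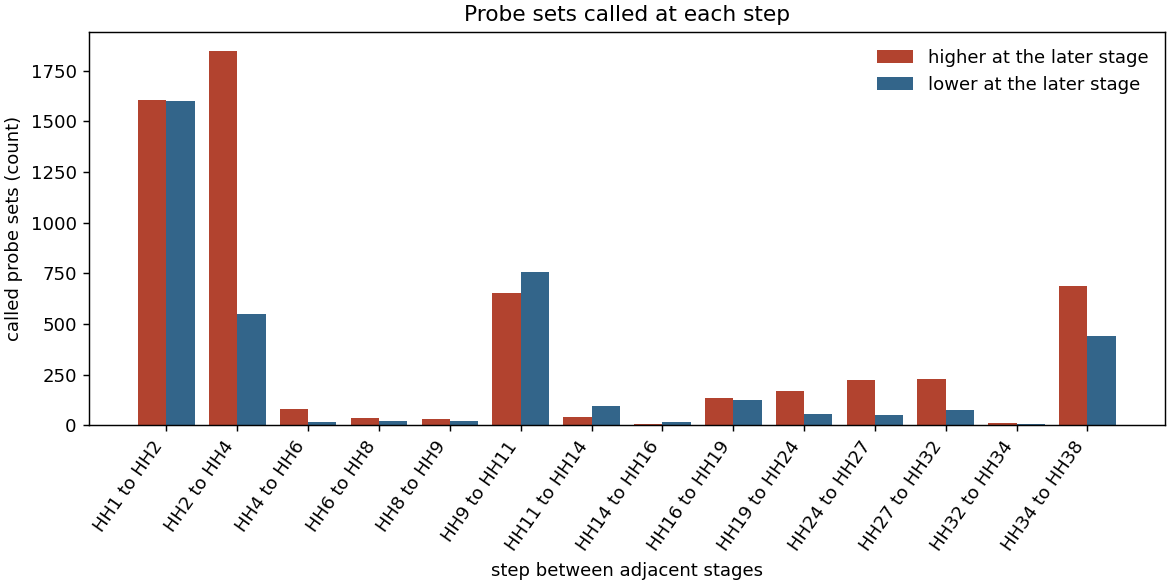
Number of probe sets called higher and lower (adjusted p below 0.05 and at least 2-fold) at each of the 14 steps between neighbouring stages. The steps to HH2 (3206), HH4 (2395), HH11 (1410) and HH38 (1126) exceed the others, the next being HH32 (302).

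The first main comparison asked what distinguishes the organ-forming embryo at HH16 from the blastoderm at HH1. Among the strongly raised genes were proteoglycan and globin genes. LUM and DCN, small proteoglycans of collagenous matrix, were below background at HH1 and rose at least 387-fold (adjusted p = 1.03e-10) and at least 261-fold (6.77e-13), LUM reaching 11860 and 12010 on the HH16 arrays. The embryonic globin gene HBZ rose at least 506-fold to 42260, HBBR at least 437-fold to 35600 and HBA1 at least 394-fold to 37230, each with 1 of 2 HH1 arrays above background. That array was HH1 replicate 2 for all of them (HBZ 241.2, HBBR 229.4, HBA1 309.1). These bounds hold for the stage mean and not for that pool alone. PTPRZ1, a neural receptor phosphatase (at least 120-fold), TSPO2 (at least 130-fold), HOXC9 (at least 47.3-fold) and RHOJ, an endothelial GTPase (at least 14.3-fold), rose from below background. The mesenchymal cadherin CDH11 rose at least 164-fold with 1 HH1 array above background.

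Strong falls from HH1 to HH16 were those of BPIFCB (at least 432-fold, adjusted p = 2.81e-09), whose HH1 signals were 11640 and 14880, of ENS-3 (at least 90.2-fold) and of NOXO1, an organizer of NADPH oxidase (at least 77.4-fold). GSC, a transcription factor of the organizer, fell at least 54.3-fold from 1653, and TGM4, a transglutaminase, at least 36.3-fold. VSTM2A (at least 20.5-fold), VNN2 (at least 7.67-fold), ARC (at least 6.69-fold) and RGNL (at least 4.72-fold) also fell. DDX4, an RNA helicase of the germ line, fell from 3065 to 50.46 (-5.93 ± 0.656).

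In all, 7338 of 29600 probe sets (24.8%) were called, 4439 higher and 2899 lower at HH16, from 2435 and 1826 genes. The median change of all probe sets was 0.0411, and -0.116 after scaling to the 75th percentile, which gave 3836 higher and 3733 lower.

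Early embryonic genes were lower at HH16. Of 23 primitive streak genes 13 were lower and 4 higher (camera adjusted p = 0.0015, 0.0471 with an estimated correlation). EOMES, a mesendoderm factor, fell at least 48.6-fold with 1 HH16 array above background, and TBX6 at least 6.09-fold. Of 10 epiblast and pluripotency genes 5 were lower and 0 higher (0.00615, 0.121 with an estimated correlation), led by TFAP2C (-3.53 ± 0.266), CDX2 (-2.80 ± 0.322) and SALL4 (-2.21 ± 0.131). Of 13 oocyte and maternal genes 7 were lower and 0 higher, or 8 and 0 adjusted over the list alone (0.0179, 0.0911 with an estimated correlation). They included DAZL, a germ cell RNA-binding protein (-3.29 ± 0.384). The primordial germ cell list, which shares DDX4 and DAZL with it, had 3 of 8 lower and 1 higher, or 6 and 1 adjusted over the list alone, and its test did not pass (0.221).

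Patterning genes were higher. All 8 measured Hox genes of groups 1 to 4 rose (camera adjusted p = 6.41e-06, 0.0284 with an estimated correlation), HOXD4 at least 76.6-fold with 1 HH1 array above background, HOXA3 by 5.99 ± 0.173 and HOXB3 by 5.74 ± 0.125. All 9 of groups 5 to 8 rose (9.24e-05, 0.0865 with an estimated correlation), HOXD8 at least 11.2-fold. Of 11 in groups 9 to 13, 9 rose and 0 fell (0.0015, 0.0691 with an estimated correlation), HOXD10 at least 24.1-fold. Of 16 somite genes 11 were higher and 1 lower (0.0145, 0.16 with an estimated correlation), with TWIST1 at least 94.4-fold and PAX7 at least 10.7-fold higher. Of 19 limb bud genes 13 were higher and 1 lower, or 14 and 1 adjusted over the list alone (0.00108, 0.0152 with an estimated correlation). PRRX1, a factor of limb mesenchyme, rose by 5.26 ± 0.141 and MEIS2 by 4.71 ± 0.814.

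Of 14 neural progenitor genes 12 were higher and 1 lower (camera adjusted p = 0.000186, 0.151 with an estimated correlation). ZIC1 rose by 6.19 ± 0.273 to 5312 and NES, the gene of the intermediate filament nestin, by 4.36 ± 0.201. Of 14 neural crest genes 8 were higher and 0 lower (0.00377, 0.147 with an estimated correlation), among them TFAP2B (4.10 ± 0.258) and SOX10 (2.96 ± 0.414). Of 23 neuron genes 13 were higher and 0 lower (0.00251, 0.0865 with an estimated correlation), with ISL1 rising by 4.70 ± 0.314, ELAVL4 by 3.88 ± 0.253 and NCAM1 at least 16.7-fold.

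Heart, vessel and blood lists moved up together with skeletal ones. Of 18 cardiac muscle genes 14 were higher and 1 lower (camera adjusted p = 1.92e-06, 0.0278 with an estimated correlation). MYH15 rose at least 145-fold to 4992 with 1 HH1 array above background, CSRP3 at least 30.6-fold and the heart factor NKX2-5 at least 8.22-fold. Of 16 endothelial genes 14 were higher and 1 lower (8.52e-06, 0.0192 with an estimated correlation), with CDH5, the cadherin of endothelial junctions, at least 84.9-fold and the angiopoietin receptor TEK at least 19.7-fold higher. Of 14 erythroid genes 11 were higher and 1 lower (0.000186, 0.147 with an estimated correlation), and all 5 globin genes in that list rose (0.000187, 0.154 with an estimated correlation). Of 24 skeletal muscle genes 15 were higher and 1 lower (0.00316, 0.108 with an estimated correlation), MYL1 at least 23.1-fold and the myogenic factor MYF5 at least 8.01-fold. Of 18 cartilage genes 11 were higher and 0 lower (0.000674, 0.0967 with an estimated correlation), with COL2A1, the main collagen of cartilage, rising by 4.69 ± 0.257. Of 17 bone and connective tissue genes 10 were higher and 1 lower, or 11 and 1 adjusted over the list alone (0.000186, 0.109 with an estimated correlation).

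The remaining lists did not pass the camera test between HH1 and HH16. Liver genes had 10 of 25 higher and 4 lower (adjusted p = 0.0589), and TTR, a thyroid hormone carrier, rose by 5.38 ± 0.132. Their test passed after 75th percentile scaling (0.0225), without the filter (0.0458), with the mean of a gene's probe sets (0.0279), without HH2 replicates 1 or 2 (0.0411) and without HH16 replicate 1 (0.0116). The lens list passed after 75th percentile scaling (0.0481), and the kidney list after that scaling (0.0389), with the mean of a gene's probe sets (0.0397) and without HH1 replicate 2 (0.0487). Counts of higher and lower genes were 7 and 5 of 16 for yolk sac (0.869), 5 and 0 of 16 for lens (0.105), 5 and 1 of 11 for kidney (0.0718), 7 and 2 of 15 for gut and pancreas (0.274; 7 and 3 adjusted over the list alone) and 4 and 1 of 9 for glia (0.555). They were 4 and 1 of 10 for pigment cells (0.555), 4 and 2 of 12 for epidermis (0.81), 4 and 2 of 12 for leukocytes (0.869), 1 and 0 of 7 for retina (0.672) and 1 and 0 of 6 for lung (0.81). Cell cycle genes had 3 and 0 of 25 (0.776), ribosomal protein genes 1 and 0 of 44 (0.292), oxidative phosphorylation 1 and 1 of 32 (0.541), glycolysis 1 and 3 of 16 (0.298) and heat shock and immediate early genes 4 and 1 of 14 (0.781). Within them ASL1 rose at least 140-fold, the water channel AQP1 by 6.82 ± 0.341 and the collagen chaperone SERPINH1 by 4.29 ± 0.153, while the glucose transporter SLC2A14 fell by 4.76 ± 0.244 and the transporter SLC34A2 by 5.02 ± 0.552. For leukocytes the median (0.379) and mean (0.506) were above 0 and the test pointed down, and for heat shock genes the median was -0.0248, the mean 0.225 and the test pointed up. Adjusted over the list alone, the counts of the other lists were those given. Of the 18 lists called, 15 up and 3 down, 4 and 1 held with an estimated correlation.

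The second main comparison asked what the late embryo at HH38 had gained or lost since HH16. Among the strongly raised genes were a myosin, keratin and plasma protein genes. MYH1B, a myosin heavy chain of fast muscle, rose at least 429-fold to 13680 (adjusted p = 1.86e-08), with 1 of 2 HH16 arrays above background. KRT5 (at least 275-fold) and KRT6A (at least 66.3-fold), keratins of stratified epithelium, EPYC, a cartilage proteoglycan (at least 65-fold), and SPP2 (at least 576-fold, adjusted p = 5.91e-13) rose from below background. So did LECT2 (at least 277-fold), the parvalbumin family gene OCM3 (at least 460-fold), PIT54 (at least 27.5-fold), the beta-defensin AvBD1 (at least 228-fold) and the pepsinogen gene PGA3 (at least 161-fold, with HH38 arrays at 10320 and 2324).

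Genes that fell included HINTW, a gene of the female-specific W chromosome, from 22000 to below background (at least 584-fold, adjusted p = 5.78e-13). PRTG fell from 9896 to 61.56 (-7.33 ± 0.124, 4.97e-21), its relative IGDCC3 at least 70.3-fold and LIN28B at least 27.9-fold. HBZ fell from 42260 to 172.7 (-7.94 ± 0.602). HNRNPKL (at least 28.6-fold) and the W-linked SPIN1L (at least 8.78-fold) fell to below background. So did the amino acid transporter SLC7A9 (at least 7.75-fold) and HAND1, a factor of heart and lateral mesoderm (at least 5.19-fold). The W chromosome list was written with HNRNPKW, a W-linked gene, and whether HNRNPKL is that gene was not checked. HOXB1 fell at least 34.7-fold with 1 HH38 array above background.

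In all, 5947 probe sets (20.1%) were called, 3616 higher and 2331 lower at HH38, from 2051 and 1525 genes. The median change of all probe sets was 0.0463. It was -0.15 after quantile normalization, which gave 3006 higher and 3467 lower, and -0.119 after 75th percentile scaling, with 3063 and 3304, so that most calls were then lower. With HH34 in place of HH38, an alternative chosen after the data were seen, 1404 were lower. Both HH38 arrays differed from the other 28 in the 3' to 5' ratio of the actin control, 2.48 and 2.99 against 1.54 to 2.01, and in W-linked genes, whose brightest probe sets lay below background there.

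Liver genes rose as a group, with 21 of 25 higher and 0 lower at HH38, or 22 and 0 adjusted over the list alone (camera adjusted p = 6.11e-13, 0.0128 with an estimated correlation). ALB reached 44510 from 89.22 (8.96 ± 0.34), FETUB rose at least 296-fold with 1 HH16 array above background, and the protease inhibitor SPIA1 rose at least 120-fold. Of 24 skeletal muscle genes 18 were higher and 1 lower, or 20 and 1 adjusted over the list alone (1.05e-06, 0.0152 with an estimated correlation). MYBPC1 rose from 54.82 to 8039 (7.20 ± 0.658), and MYLPF at least 12.5-fold. Of 23 neuron genes 16 were higher and 0 lower (1.92e-06, 0.0128 with an estimated correlation), with the synaptic gene SNAP25 rising by 5.37 ± 0.244 and the glutamate receptor GRIA2 by 3.89 ± 0.192. Of 12 leukocyte genes 10 were higher and 0 lower (6.93e-06, 0.0128 with an estimated correlation), CD74, the invariant chain of class II antigen-presenting molecules, by 3.69 ± 0.186. Of 10 pigment cell genes 8 were higher and 0 lower (0.000335, 0.0128 with an estimated correlation), with TYRP1, a melanin enzyme, rising by 6.48 ± 0.657 and PMEL at least 53.3-fold. These changes fell in the same comparison as the actin ratios of 2.48 and 2.99 and the W-linked genes below background by their brightest probe sets.

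Skeletal tissue, glia and skin followed. Of 17 bone and connective tissue genes 15 were higher and 0 lower (camera adjusted p = 3.97e-06, 0.0691 with an estimated correlation), with IBSP at least 27.3-fold and TNMD at least 90.9-fold higher, each above background on 1 HH16 array. Of 18 cartilage genes 11 were higher and 1 lower (0.00061, 0.0967 with an estimated correlation), COL10A1 at least 33.7-fold and ACAN at least 11-fold. Of 9 glial genes 3 were higher and 0 lower (0.00783, 0.0849 with an estimated correlation), the myelin genes PMP22 (2.42 ± 0.142), MBP (2.17 ± 0.233) and MOG (2.13 ± 0.369). Of 12 epidermis genes 4 were higher and 2 lower (0.0198, 0.188 with an estimated correlation), KRT14 rising (2.47 ± 0.195) and KRT24 falling (-2.38 ± 0.143), and with HH34 in place of HH38 the list pointed down (0.0657). Of 16 yolk sac genes, 6 of them shared with the liver list, 6 were higher and 1 lower (0.0388, 0.176 with an estimated correlation). That call ended without HH16 replicate 1 (0.0763), without HH38 replicate 2 (0.0674), with the mean of a gene's probe sets (0.0941) and with HH34 in place of HH38 (0.0563).

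Cell cycle genes fell, with 21 of 25 lower and 0 higher (camera adjusted p = 1.23e-15, 0.000729 with an estimated correlation). The mitotic kinase PLK1 fell by 2.02 ± 0.11, as did the replication gene MCM5 (-1.71 ± 0.105) and BIRC5 (-1.67 ± 0.0785). Epiblast genes had 6 of 10 lower and 1 higher (0.012, 0.147 with an estimated correlation), with SALL4 falling by 4.81 ± 0.131 and LIN28A at least 24.3-fold. Of 8 Hox genes of groups 1 to 4, 6 fell and 0 rose (0.0015, 0.107 with an estimated correlation), HOXD4 (-2.55 ± 0.34) and HOXA4 (-1.82 ± 0.218) among them. Oxidative phosphorylation genes moved down by a small amount (median -0.205, 0.0187, 0.471 with an estimated correlation) with 0 of 32 genes called. That list call ended after quantile normalization (0.497), with the stricter filter (0.0532) and with HH34 in place of HH38 (0.0659). The same HH38 arrays carried the higher actin ratio and the W-linked genes below background by their brightest probe sets.

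Other lists did not pass at HH38. Counts of higher and lower genes were 0 and 5 of 14 for neural progenitors (0.06), 0 and 3 of 5 for globins (0.0546), 0 and 5 of 16 for somite genes (0.127), 0 and 4 of 9 for Hox groups 5 to 8 (0.154) and 0 and 5 of 11 for Hox groups 9 to 13 (0.234). They were 1 and 4 of 23 for primitive streak genes (0.649; median 0.0225, mean -0.388, test down), 1 and 1 of 14 for neural crest (0.555), 6 and 3 of 18 for cardiac muscle (0.193), 3 and 4 of 14 for erythroid genes (0.326) and 3 and 1 of 16 for endothelium (0.672). Oocyte genes had 0 and 3 of 13 (0.651), germ cells 0 and 2 of 8 (0.776), lens 1 and 2 of 16 (0.696), retina 1 and 1 of 7 (0.651), limb bud 1 and 4 of 19 (0.512), kidney 2 and 4 of 11 (0.776), gut and pancreas 6 and 4 of 15 (0.503) and lung 2 and 0 of 6 (0.541). Ribosomal protein genes had 0 and 0 of 44 (0.873), glycolysis 2 and 0 of 16 (0.25) and heat shock and immediate early genes 4 and 1 of 14 (0.555). SOX3, a factor of neural progenitors, fell by 3.47 ± 0.165, the intestinal gene FABP2 rose at least 14.5-fold, CPA1, a pancreatic carboxypeptidase, at least 12.3-fold, and the immediate early factor EGR1 by 4.02 ± 0.317. The neural progenitor and globin lists passed without the filter (0.0466 and 0.0434), with a pseudocount (0.0318 and 0.0321), with array weights (0.0489 and 0.0485) and with the mean of a gene's probe sets (0.0242 and 0.0344). Neural progenitors also passed without HH2 replicates 1 or 2 (0.0393, 0.04) and without HH9 replicates 1 or 2 (0.0441, 0.0444). Globins passed without HH1 replicates 1 or 2 (0.0287, 0.0292), either HH6 array (0.0407), HH16 replicate 2 (0.044) or HH38 replicate 2 (0.0491). Hox groups 9 to 13 passed with a pseudocount (0.0386) and the lens list with HH34 in place of HH38 (0.0208). Adjusted over the list alone, the counts were those given except where stated. Of the 14 lists called, 10 up and 4 down, 5 and 1 held with an estimated correlation.

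**Figure D2:**
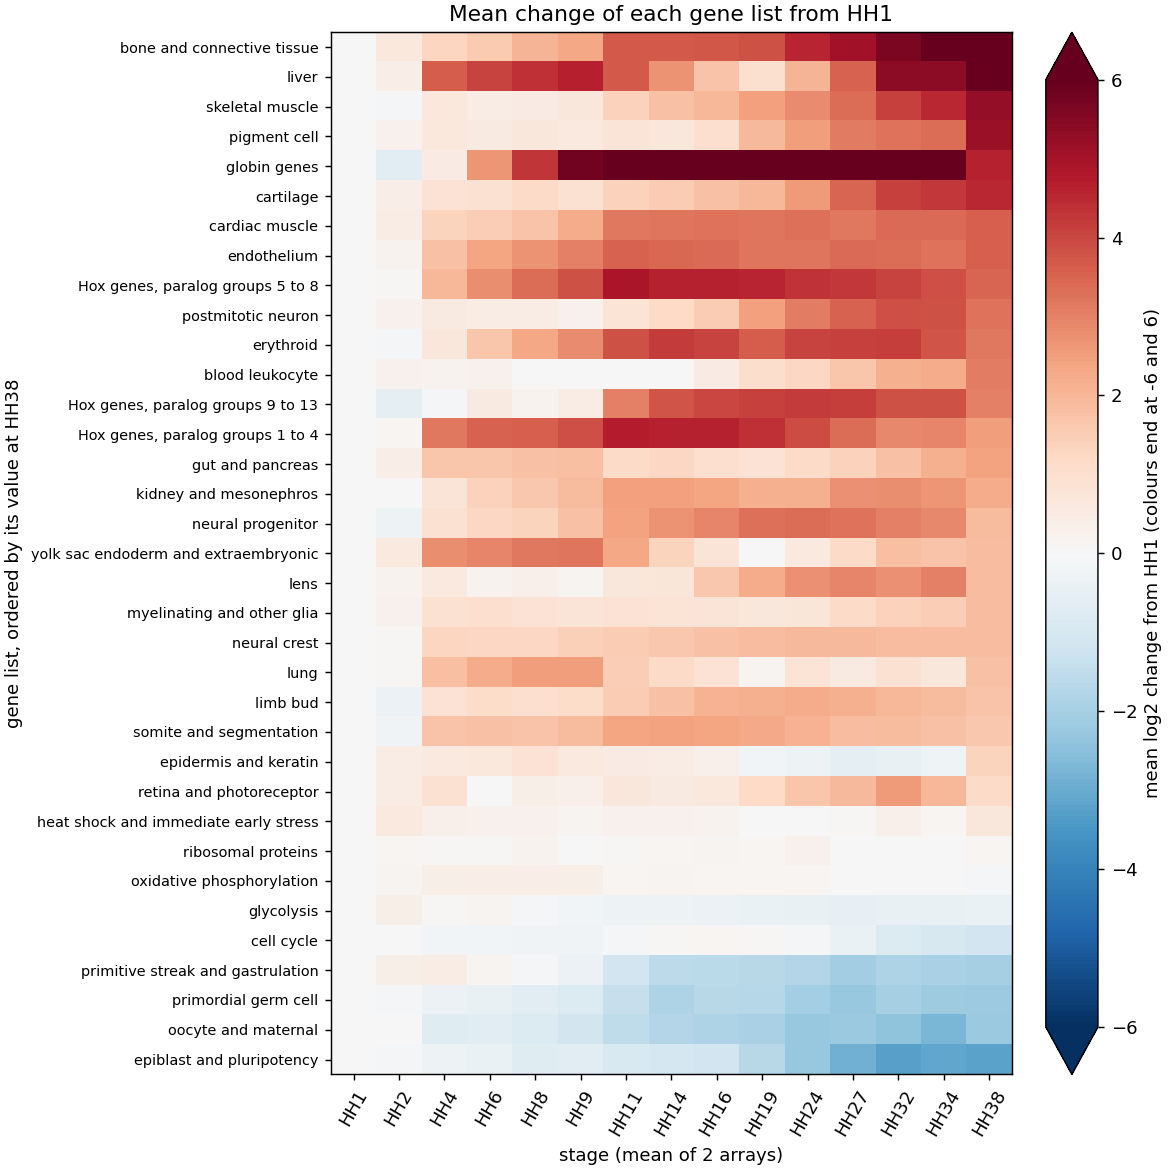
Mean log2 change from HH1 of the members of each of the 35 tested gene lists at each stage. Lists are ordered by the value at HH38, with colours ending at -6 and 6. The W chromosome list is not drawn. At HH4 the liver (3.61), Hox groups 1 to 4 (3.18) and yolk sac (2.81) lists stand highest, and at HH38 the epiblast list (-3.23) lies lowest.

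A further comparison asked which genes stood apart at HH16 from both ends of the course. Higher at HH16 than at both HH1 and HH38 were the embryonic globins HBZ, HBBR and HBE, of which HBE went from 1164 to 35340 and back to 1150 (4.93 ± 0.239 and -4.94 ± 0.239). IGDCC3 rose at least 44.3-fold with 1 HH1 array above background and fell at least 70.3-fold, and HES6, a neurogenic regulator, rose by 5.04 ± 0.251 and fell by 4.38 ± 0.251. GREB1 (at least 34.8-fold up, then -4.65 ± 0.337), HAND1 (at least 6.34-fold up, at least 5.19-fold down) and SLC7A9 (at least 9.47-fold up, at least 7.75-fold down) followed the same course. Lower at HH16 than at both ends were MT4, a metallothionein, at 14340, 1162 and 13360 (-3.63 ± 0.0882 and 3.52 ± 0.0882), the thyroid hormone activating enzyme DIO2 (-3.90 ± 0.292 and 3.54 ± 0.292) and ST8SIA3 (-3.50 ± 0.39 and 3.24 ± 0.39). AREG (at least 6.37-fold down, at least 10.1-fold up), KMO (at least 5.9-fold and at least 9.09-fold), VNN2 (at least 7.67-fold and at least 6.77-fold) and VSTM2A (at least 10.9-fold and at least 12.3-fold, by another probe set than above) did the same.

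In all, 378 probe sets were higher and 557 lower at HH16 than at both ends. Independent lists of these sizes would share 350 and 354. Both comparisons use the HH16 arrays, so the lists are not independent and these values do not show whether the counts exceed what unrelated changes would give. With 1 HH16 array against HH1 and the other against HH38, the counts were 293 and 304 higher and 412 and 390 lower in the 2 arrangements. Lists called with 1 HH16 array have other sizes, so 350 and 354 are not the values to set beside these counts. The HH38 end of this comparison carried the higher actin ratio and the W-linked genes below background by their brightest probe sets, and with HH34 in place of HH38 the count higher at HH16 was 250.

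Gene lists differed in the stage from which they stayed apart from HH1 at every later stage. Some lists share members, and 6 of 19 limb bud genes and 6 of 14 neural crest genes are also in another list. A first stage therefore dates the list and not the tissue it is named after. Hox groups 1 to 4 and 5 to 8, neural crest, cardiac muscle and endothelium were higher than at HH1 from HH4 on at every later stage, erythroid and bone and connective tissue from HH6, cartilage from HH8, neural progenitors and limb bud from HH9 and Hox groups 9 to 13 from HH11. Neuron and skeletal muscle genes followed from HH14 and liver from HH24, and leukocyte and pigment cell genes at HH38, the stage with the higher actin ratio. Liver genes were also higher from HH4 to HH14 (mean change 4.65 at HH9, camera adjusted p = 1.15e-09) and not called at HH16 (1.70, 0.0572) and HH19 (0.97, 0.335). Lists that did not stay apart to the end could still be called at earlier stages. Somite genes were higher from HH4 (camera adjusted p = 0.017) to HH19 (0.0236) and not called from HH24 on (0.0547 at HH24). Epiblast genes were lower from HH6, primitive streak and oocyte genes from HH11 and cell cycle genes from HH27. In the streak list TBXT, the mesoderm factor brachyury, was highest at HH4 (10910) and stood at 140.1 at HH38. The 16 higher and 4 lower lists that stayed apart at every later stage passed camera with its preset correlation. With an estimated correlation 18 of the 20 had no such stage, and 0 of 20 kept the stage given.

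Hox genes with higher paralog numbers tended to rise over HH1 at later stages. Of 28 Hox genes measured, 26 had an onset, the first stage called higher than HH1. Across these 26 genes, which are not independent replicates, paralog number and onset stage had a Spearman rho of 0.879 (two-sided permutation p = 1e-05, the smallest that 1e+05 resamples can give). With the stage of the highest mean in place of the onset, over all 28 genes measured, rho was 0.473 (permutation p = 0.012). HOXB1 and HOXA2 had their onset at HH2, and all 8 genes of groups 1 to 4 by HH4. An onset is a rise over HH1 and not a first signal, and HOXB1 already read 244.1 at HH1, above background. Other genes, such as HOXA2 (8.66), HOXB6 (1.9) and HOXD10 (1.95), had HH1 means below the background of both HH1 arrays (28.9 and 32.8). Their onsets therefore rest in part on signals under the floor. Onset ran from HH4 to HH11 for the 9 genes of groups 5 to 8. For the 9 of groups 9 to 13 it ran from HH4 (HOXA9) to HH16 (HOXC11), and for 7 of them it was at HH11 or later. HOXA10 and HOXC13 had no onset. HOXB1 peaked at HH4 (3107), HOXA3 at HH11 (2956) and HOXD13 at HH27 (509.3).

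**Figure D3:**
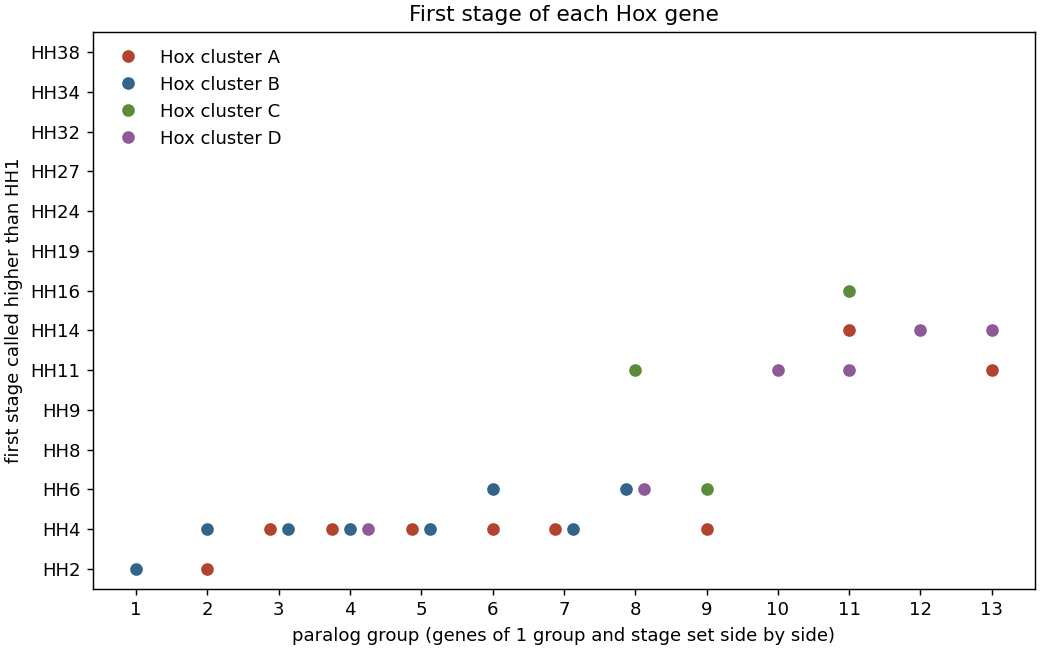
Onset stage against paralog group of 26 Hox genes, 1 point per gene, coloured by cluster A to D. Genes of groups 1 to 4 lie at HH2 or HH4, and 7 of the 9 of groups 9 to 13 lie at HH11 or later.

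Some globin genes fell during the later part of the course and others stayed high. HBZ stood at 42260 at HH16, 44630 at HH24 and 34820 at HH27, and then at 6653 at HH32, 2184 at HH34 and 172.7 at HH38. The call of HBZ from HH27 to HH32 ended without any 1 array of these stages, with log2 changes of -2.28 to -2.49. HBE went from 35340 at HH16 to 18080 at HH32, 9663 at HH34 and 1150 at HH38 (-4.94 ± 0.239 between HH16 and HH38), and HBBR to 13210, 6284 and 834.1 (-5.42 ± 0.927). The alpha-type genes HBA1 (37230 at HH16, 41650 at HH38) and HBAD (33980 and 37460) were not called between these stages. From HH34 to HH38, 3 of the 5 globins were lower and 0 higher (camera adjusted p = 0.036, 0.561 with an estimated correlation), on the arrays with the higher actin ratio.

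**Figure D4:**
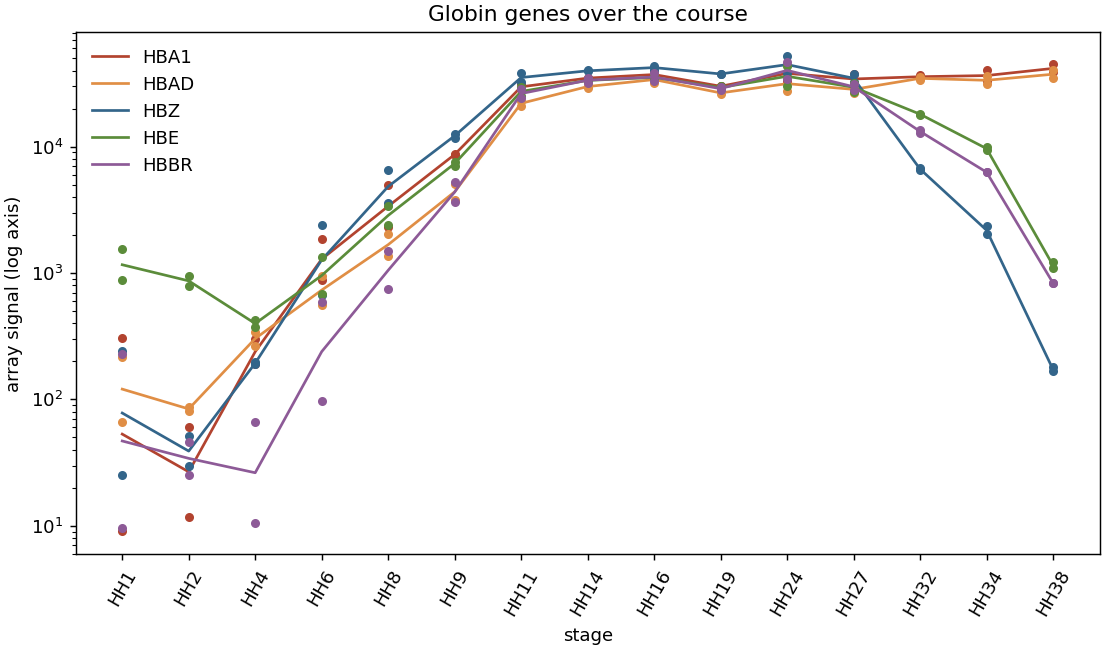
Signal of the globin genes over the 15 stages on a log axis, with points for single arrays and lines through the geometric mean of each stage. HBZ, HBE and HBBR fall after HH27 while HBA1 (41650) and HBAD (37460) stay high at HH38.

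W-linked genes were measured to describe the sex of the pools, which the labels give as mixed. Females carry the W chromosome and males do not. The brightest HINTW probe set read 13070 to 35520 on the 28 arrays up to HH34 and 3.56 and 30.3 on the HH38 arrays, below background on both (at least 468-fold lower than at HH34, adjusted p = 1.13e-11). By the brightest probe set of each, SPIN1L (at least 35.9-fold), LOC374195 (at least 17.4-fold) and UBAP2L2 (at least 4.09-fold) were also below background on both HH38 arrays after being above it at HH34. A dimmer UBAP2L2 probe set was above background on both HH38 arrays (85.3 and 42.6). Before HH38 the 2 pools of some stages differed. The brightest HINTW probe set read 26930 and 13110 at HH14 and 27180 and 13070 at HH24. It was higher in replicate 1 at each stage from HH6 to HH24 and at HH34, and in replicate 2 at the other stages before HH38. At HH14 the brightest probe sets of SPIN1L (589.9 and 164.2), LOC374195 (622 and 180) and UBAP2L2 (223 and 62.2) were also higher in replicate 1. Dimmer UBAP2L2 probe sets did not all differ this way. Whether the share of females differed between these pools was not tested. Between HH1 and HH16, 0 of the 4 W-linked genes measured in the list were called, and between HH16 and HH38 all 4 were lower.

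**Figure D5:**
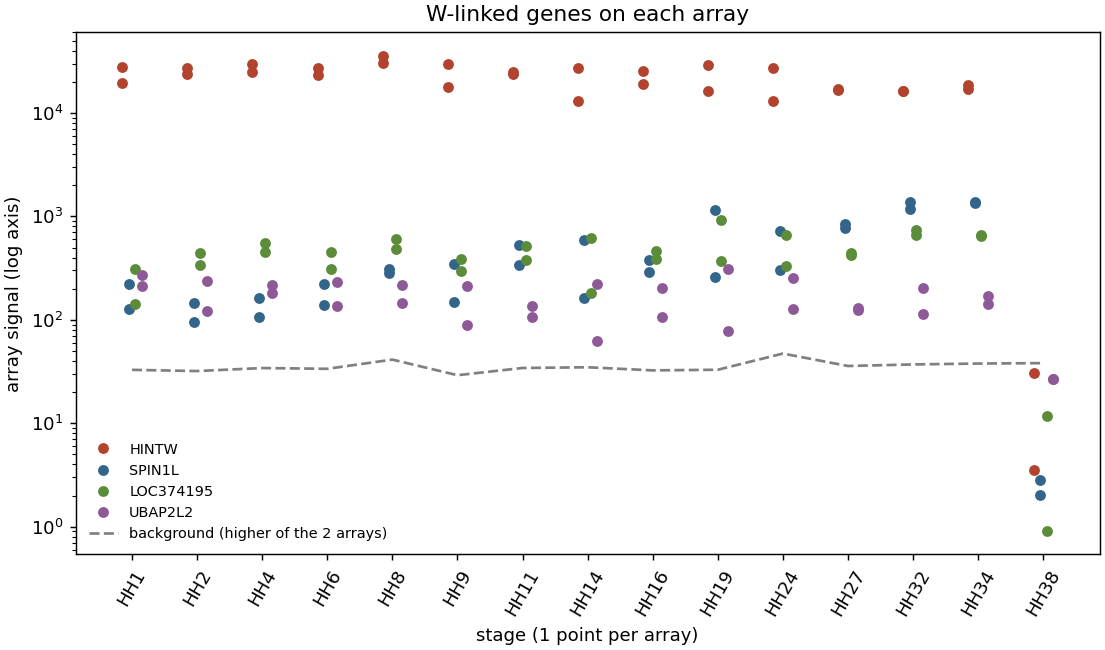
Signal of the brightest probe set of each of 4 W-linked genes by stage on a log axis, 1 point per array, with the background of the arrays as a dashed line. Both HH38 arrays lie below background for each of these probe sets, HINTW at 3.56 and 30.3 against 13070 to 35520 on the other 28 arrays.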

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

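The screen of probe sets outside the comparisons was applied after the data had been seen, and no test of an explanation was run in this part. Of 746 probe sets for other organisms or reporter genes, 1 for another organism had both arrays of a stage above the 75th percentile of the chicken probe sets, a signal in data the comparisons do not use. Its highest stage mean was 5384 and its lowest 548.5, while the highest of the others was 150.5. It was higher at HH38 than at HH1 by 2.76 ± 0.37 (limma adjusted p = 5.37e-05) and than at HH16 by 1.81 (0.0372), and between HH1 and HH16 it was not called (0.955, 0.543). Whether its probes bind a chicken transcript or one of another origin was not tested, nor was a biological explanation.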

How the results depend on the processing

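HH34 in place of HH38, HH2 in place of HH1 and leaving out the 4 arrays of HH8 and HH24 were chosen only after the results were seen. Across 28 results and 19 settings, 329 values were compared, and a count was taken as changed beyond 1.5 times its main value. The cause was not tested for the changes that follow, except that a test by adjusted p alone or below 0.01 widens or narrows the calls by construction. The step to HH34 called 29 probe sets after quantile normalization, 9 without the variance trend and 73 with array weights. The step to HH8 called 29 with a pseudocount, 35 without the trend and 24 with array weights, that to HH16 10 with a pseudocount and 11 without the trend, that to HH9 13 and that to HH32 554 with array weights. With a pseudocount 7 lists were lower at HH38 than at HH16.

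By adjusted p alone the steps called 8252 (HH2), 5680 (HH4), 157 (HH6), 101 (HH8), 3585 (HH11), 279 (HH14), 35 (HH16), 624 (HH19), 757 (HH24), 948 (HH27), 1493 (HH32), 30 (HH34) and 3826 (HH38). HH16 against HH1 then gave 7100 higher and 5651 lower, HH38 against HH16 5494 and 6074, and HH16 apart from both ends 1844 and 1225. With adjusted p below 0.01 the steps called 38 (HH6), 14 (HH8), 15 (HH9), 70 (HH14), 2 (HH16), 146 (HH19), 104 (HH24), 152 (HH27), 169 (HH32), 5 (HH34) and 710 (HH38). An estimated correlation left 4 lists higher and 1 lower at HH16 than at HH1, 5 and 1 at HH38 than at HH16, and a first stage for 1 higher and 1 lower list. With fry 26 lists were higher and 5 lower at HH16, and 14 lower at HH38. With HH34 in place of HH38, 1404 probe sets were lower than at HH16 and 250 were higher at HH16 than at both ends, and the epidermis list pointed down (0.0657). With HH2 in place of HH1, 1716 were lower at HH16.

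With 1 array left out, the other array of its stage is assumed to vary like the other stages. Counts then ranged from 55 to 211 at HH6, 21 to 165 at HH8, 45 to 187 at HH9, 85 to 163 at HH14, 19 to 65 at HH16, 170 to 274 at HH19, 124 to 593 at HH27 and 10 to 35 at HH34. The Hox rho was 0.473 with the stage of the highest mean, over all 28 Hox genes measured. It was 0.846 to 0.884 under the other settings and 0.663 (without HH1 replicate 1) to 0.891 with 1 array left out. A block for the replicate number moved no count beyond 1.5 times (20355 for the stage effect, 1396 at HH11). Over the probe sets kept, the deviations of replicates 1 and 2 from their stage means correlated between stages at a median of 0.0037. The numbers thus showed no general pairing of the samples, although the brightest HINTW probe set read higher in replicate 1 at each stage from HH6 to HH24. Of 20 lists with a first stage, 17 kept the same stage after quantile normalization, 11 after 75th percentile scaling 11 with the mean of all probe sets and 0 with an estimated correlation. Signal over background limits folds of genes that were dim at one stage, which are given as bounds, and 65% to 72.8% of the chicken probe sets lay above background on an array.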

Other observations

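Of the tests below, those of RNA quality for the W-linked genes and for the actin ratio, of yolk sac endoderm and of the HH4 and HH11 overlap were chosen only after the results were seen. Some genes rose at HH4 and fell at HH11. Of 1847 probe sets called higher at HH4 than at HH2 and 758 called lower at HH11 than at HH9, comparisons without a shared array, 304 (40.1% of the latter, 221 genes) were in both, against 47.3 for independent lists. In the opposite order 48 were in both, against 12.1, so the overlap exceeded that of independent lists in either order. APOB stood at 1.65 at HH2, 10610 at HH4, 25600 at HH9, 14370 at HH11, 161.5 at HH19 and 8070 at HH32. Its fall from HH9 to HH11 was less than 2-fold, so this probe set is not among the 304. CUBN, an uptake receptor of yolk sac endoderm, went from 6234 at HH9 to 1149 at HH11 and 102.1 at HH19. FGB, a fibrinogen chain, went from 18070 at HH9 to 1052 at HH19 and was 9918 at HH38. These genes were chosen after their values were seen.

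Lens and neural progenitor genes were lower at HH38 than at HH34. Of 16 lens genes 6 were lower and 0 higher (camera adjusted p = 0.00645, 0.281 with an estimated correlation), with ASL1 at 13090 at HH34 and 2864 at HH38, and of 14 neural progenitor genes 7 were lower (0.000231, 0.281 with an estimated correlation). The W-linked genes below background by their brightest probe sets and the higher actin ratio lie on the same HH38 arrays.

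The brightest probe set of each of 4 W-linked genes fell below background on both HH38 arrays, while a dimmer UBAP2L2 probe set did not (85.3 and 42.6), although the labels give mixed sex. A loss of RNA quality was tested on other bright probe sets. Of 1383, 0% fell by at least 50% of HINTW's log2 fall. With background in place of HINTW's HH38 signals the change is -8.87, 0 of them reached 50% of that either, and the largest among the 1383 was -3.07, so a general loss of signal does not account for it. Pools of few or no female embryos remain a candidate explanation. Males carry a second Z chromosome, so Z-linked genes should then be higher. The median change of 54 measured Z-linked genes from HH34 to HH38 was 0.238, which is 0.296 above random genes of like level, and 0% of 10000 random lists were as high. Other steps gave differences of -0.12 to 0.219, so the margin over them is small. The Z list was written from textbook knowledge, other changes at HH38 could move these genes too, and with both HH38 pools alike the sex of the pools and the stage were not separated in other HH38 results.

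The step from HH9 to HH11 changed more probe sets (1410) than its neighbours. Scaling of the arrays does not account for it, since 1321 were called after quantile normalization. Less yolk sac and other extraembryonic endoderm in the pools from HH11 on is a candidate explanation that could not be decided. The median change of its list was -0.997, just short of the 2-fold fall set as the bound, and 6 of 16 genes were lower. Of the 16 genes 6 are also in the liver list and 7 in another list, and 4 of the 6 lower ones are in no other list. The most abundant at HH9 all had lower stage means at HH11, but by unequal amounts. They were TTR at 32890 and 28570, APOA1 at 30050 and 10750, APOB at 25600 and 14370 and CUBN at 6234 and 1149. The falls of TTR and APOB were less than 2-fold. A change in the embryo itself was not tested and remains open.

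The actin 3' to 5' ratio on the HH38 arrays lay 6.02 SD above the other 28 arrays. Loss of RNA quality at HH38 could raise such ratios in every control. The EEF1A1 ratio lay 2.42 SD above the others and that of GAPDH 1.15 SD, so the controls did not move alike, and this explanation cannot be told apart from a change in actin transcripts with stage. The labels give no RNA quality values.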
